A study of Mus musculus with 199 samples.

How the data were processed

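RNA was measured by sequencing of mouse liver in 121 of the 199 samples of the series. The other 78 samples (chromatin immunoprecipitation, its input and chromatin accessibility) were not analysed here. Each library has a table of raw counts per gene name, which per the file headers were made with featureCounts 1.5.1 on the GENCODE M12 annotation of GRCm38, and the submitters' processing notes name STAR 2.5.2 for alignment. The counts, as deposited, are not normalised. Per the file headers, exons were merged by gene name, reads that map to several places were counted at each of them, and strand was not used. Values of genes with near-identical copies therefore share reads, and antisense reads are counted with a gene. No base-level or exon-level values were used here.

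Counts of 49568 gene names were analysed with edgeR 4.0.16 in R 4.3.3. Each of the 4 experiments was fitted on its own, with a group for each combination of treatment or genotype and time. Genes with low counts were removed by filterByExpr on these groups, libraries were scaled by TMM, and quasi-likelihood F tests were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. All tests were two-sided or F tests. NR against H2O and LNKO against controls were compared as the mean over the 6 times, as an interaction with time, and as 24 h cosine and sine terms per arm (rhythm within an arm, and the difference of the terms between arms). The controls of the Nampt experiment pool both genotypes as the sample titles do, and the genotypes were also compared with each other. The Bmal1 and Sirt1 experiments were each fitted with all 4 groups, so that arms with 2 libraries borrow the spread of the others. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Amplitude, peak time and their errors came from least squares on log2 CPM (counts per M counts of a library) with a prior count of 2. Libraries are separate samples by their labels, and adjusted p-values measure the spread between these samples.

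Before the data were examined, 42 gene lists, the comparisons, most alternatives and the rule for named genes were fixed. The lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, and members were counted at adjusted p over all genes and adjusted over the list alone. Among genes with a mean log2 CPM of at least 2, the rule names the targeted gene, the 5 called genes with the largest rise and the 5 with the largest fall, and for F tests the 10 with the smallest p. It also names the 3 members with the smallest p of the core clock, clock output, heat shock and NAD+ metabolism lists and of the 3 other lists with the smallest camera p, and any core clock gene. Gene models with provisional names are passed over, and some genes that the rule names are not reported here. The genes named at single times of day or outside the rule are said to be so or come from the interaction tests.

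Depth ran from 3.9 to 62.9 M counts per library, with a median of 18.4 M, and mitochondrial genes took 5.5 to 9.82% of counts. No library repeated another by the spread of counts between libraries of a group. The replicate numbers did not pair libraries across groups (mean correlation of residuals 0.0183 within and -0.00793 between numbers in the NR experiment, and 0.00775 and -0.00138 in the Nampt experiment), so that no block was used, except as an alternative. The tests were checked on simulated data made from these libraries. Each gene was drawn on its own around 1 mean, with the spread that edgeR estimated. Simulated genes thus did not vary together, and no simulated library stood apart. The rates below can therefore be better than in the real data, and can favour edgeR over DESeq2. In the NR comparison 97% of simulated 2-fold changes were recovered with 3.55% false calls, and in the LNKO comparison 94% with 2.69%. For NMN in wild type, 41.8% of 2-fold changes were recovered with 5.75% false calls, and DESeq2 there gave 16.9% false calls. The interaction of NMN with Bmal1 recovered 1.49% of 2-fold changes, so that a low count there says little.

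The alternatives were DESeq2 1.42.0 in place of edgeR, size factors in place of TMM, no filter on low counts, the replicate number as a block, time as 6 unordered levels in place of a cosine, the controls of each genotype alone, all 25 NMN libraries in 1 fit, and each library of a group of up to 5 libraries left out in turn. Added after seeing the data were fits without the 2 ZT0 libraries numbered apart from the rest, without the shallowest library (ctrl ZT12 replicate 2), without all ZT12 libraries of the Nampt experiment, and without 2 Sirt1 fx/fx NMN libraries named by another scheme. Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.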

Results

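Liver RNA was sequenced in 121 libraries from mice, which fall into 4 experiments. In the first, wild-type mice of 8 months drank water (H2O, 19 libraries) or nicotinamide riboside (NR, 19 libraries) for 4 months. NR, an oral precursor of NAD+, was given at 400 mg/kg. Livers were collected at 6 zeitgeber times (ZT, hours after lights on). There were 4 libraries per drink at ZT0 and 3 at each of ZT4, ZT8, ZT12, ZT16 and ZT20. In the second, mice of 8 months were fasted for 18 h. Those without hepatic Nampt (LNKO, Alb-Cre; Namptfx/fx, 20 libraries with 2 to 5 per time) were compared with 38 controls (5 to 9 per time) at the same 6 times. The controls held 18 libraries of Alb-Cre; Nampt+/+ mice and 20 of Namptfx/fx mice. The other 2 experiments used mice of 4 to 6 months, collected at ZT6. They received saline or nicotinamide mononucleotide (NMN, another precursor of NAD+) by injection, with labels of 500 mg/kg and 4 h for NMN. The groups were wild-type (3 saline, 2 NMN) and Bmal1 knockout mice (3 saline, 2 NMN), and Sirt1 fx/fx controls (4 saline, 4 NMN) and liver Sirt1 knockouts (LSKO, 3 saline, 4 NMN). By their labels, LSKO mice carried Alb-Cre and the Sirt1 fx/fx controls did not. Total counts per library, in M (mega) counts, ran from 3.9 to 62.9 M with a median of 18.4 M. The ranges were 13.5 to 26.1 M in the NR experiment, 3.9 to 43.4 M in the Nampt experiment, 28.1 to 62.9 M in the Bmal1 experiment and 26.9 to 43.8 M in the Sirt1 experiment. H2O and NR libraries averaged 19.7 ± 4.03 and 19.3 ± 2.62 M counts (SD, n = 19 each), and control and LNKO libraries 15.5 ± 6.80 M (SD, n = 38) and 17.0 ± 6.30 M (SD, n = 20).

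The first comparison asked which liver genes differed with months of oral NR, on average over the day. Many lipogenic genes were lower and some fatty acid oxidation genes were higher in NR livers. Neither list was called by camera with an estimated correlation. None of 25 cholesterol synthesis genes passed by either adjustment (median log2 fold change 0.09). Of 18 lipogenic genes measured, 11 fell and none rose (13 fell adjusted over the list alone), with a median log2 fold change of -0.40. Pklr, the liver pyruvate kinase that feeds glycolytic carbon to lipogenesis, was 2.29-fold lower (log2 fold change -1.19, SE 0.23, adjusted p = 0.00103). Elovl6, a fatty acid elongase, was 1.73-fold lower (-0.79, SE 0.16, adjusted p = 0.00189), and Acly, which makes cytosolic acetyl-CoA, 1.52-fold lower (adjusted p = 0.00124), with n = 19 per drink. Of 35 fatty acid oxidation genes, 11 rose and none fell (17 rose adjusted over the list alone), with a median of 0.25. The group includes Cyp4a31 and Cyp4a32, microsomal fatty acid hydroxylases, at 2.35-fold and 1.98-fold (adjusted p = 0.000549 and 0.000596). Cidec, which encodes a lipid droplet protein and not an enzyme of oxidation, rose 2.93-fold (log2 fold change 1.55, SE 0.30, adjusted p = 0.00105). Cyp4a14 and Cyp4a10, of the same hydroxylase family, rose 3.60-fold and 2.48-fold (adjusted p = 0.00563 and 0.00115), although reads shared among the near-identical Cyp4a genes were counted at each of them, which leaves the share of each uncertain. Cfd, an adipocyte serine protease of the complement system, showed the highest rise at 6.78-fold (log2 fold change 2.76, SE 0.49, adjusted p = 0.000596).

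Other metabolic groups were also lower with NR. Of 16 genes of glycolysis and glycogen, 6 fell (9 adjusted over the list alone), including Pygl, the liver glycogen phosphorylase (1.42-fold lower, adjusted p = 0.000117). Of 9 pericentral markers 4 fell, of 25 ER stress genes 7 fell, and of 14 cell cycle genes 4 fell (5, 10 and 4 adjusted over the list alone). Of 21 acute-phase genes 4 fell (6 adjusted over the list alone), with Saa2 at 2.79-fold lower (adjusted p = 0.0343) and Saa1 at 2.46-fold lower (adjusted p = 0.0425). These paralogs share reads, and without the H2O library of ZT4 replicate 1 their adjusted p were 0.128 and 0.157, with other single libraries also ending the call. Among 14 secreted hepatocyte proteins 5 fell and 1 rose (6 and 1 adjusted over the list alone), while 5 of 14 p53 targets rose by either adjustment. Within 26 genes of NAD+ metabolism 4 fell and 1 rose (4 and 2 adjusted over the list alone), with Qprt and Kynu, enzymes of synthesis from tryptophan, each 1.18-fold lower (adjusted p = 0.000878 and 0.00103). Hspb1, a small heat shock protein, was 1.33-fold higher (adjusted p = 0.0101) and the only one of 24 heat shock genes to change, in a list whose median (-0.00) and mean (0.03) differ in sign. Among markers of other cell types, 6 erythroid markers had a median of 0.50 (0 rose over all genes, 5 adjusted over the list alone) and 8 bile duct markers one of -0.17 (1 fell by either adjustment). In all, 1791 of 15710 tested genes differed, 890 higher and 901 lower, and 16 rose and 32 fell by over 2-fold. By camera with a preset correlation, the lipogenesis (adjusted p = 1.58e-10), fatty acid oxidation (7.66e-09), glycolysis and glycogen (1.73e-06), pericentral (0.000128), ER stress (0.000376), secreted protein (0.00292), cell cycle, acute-phase and p53 lists (0.00359 each) were called. None of the 9 calls held with an estimated correlation, with adjusted p between 0.176 (lipogenesis) and 0.741 (acute phase) with an estimated correlation.

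The next question was whether daily timing differed with NR. Clock genes cycled strongly in both drinks. Arntl (Bmal1), the activator at the core of the clock, had a fitted peak-to-trough ratio of 27.6 with H2O and 36.2 with NR, peaking at ZT22.0 ± 0.42 and ZT22.0 ± 0.39 h (SE, n = 19 each). Dbp, a PAR bZIP transcription factor that the clock drives, peaked at ZT9.82 ± 0.32 h with H2O and ZT9.68 ± 0.34 h with NR. Of 16 core clock genes, 15 were rhythmic with H2O and 15 with NR (15 each adjusted over the list alone), Rora being the exception in both (adjusted p = 0.239 and 0.479). Of 18 clock output genes, 17 and 18 were rhythmic by either adjustment. Over all genes 5219 were rhythmic with H2O and 5569 with NR, and in the test of the difference itself edgeR called 0 (1698 at an unadjusted p under 0.05, smallest adjusted p = 0.283, and 29 by DESeq2). The daily mean of some clock genes did differ. Nr1d2, a nuclear receptor that represses Arntl, was 1.29-fold higher (adjusted p = 0.00291), Per3, a period gene, 1.38-fold higher (adjusted p = 0.021), and Tef, a partner of Dbp, 1.28-fold higher with NR (adjusted p = 0.00113). Arntl had a log2 fold change of -0.29 (SE 0.10, adjusted p = 0.0591). In the core clock list 2 rose (2 rose and 1 fell adjusted over the list alone), and its median of -0.04 and mean of -0.02 had the opposite sign to its camera direction (adjusted p = 0.809). Of the clock output genes 6 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.11).

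**Figure D1:**
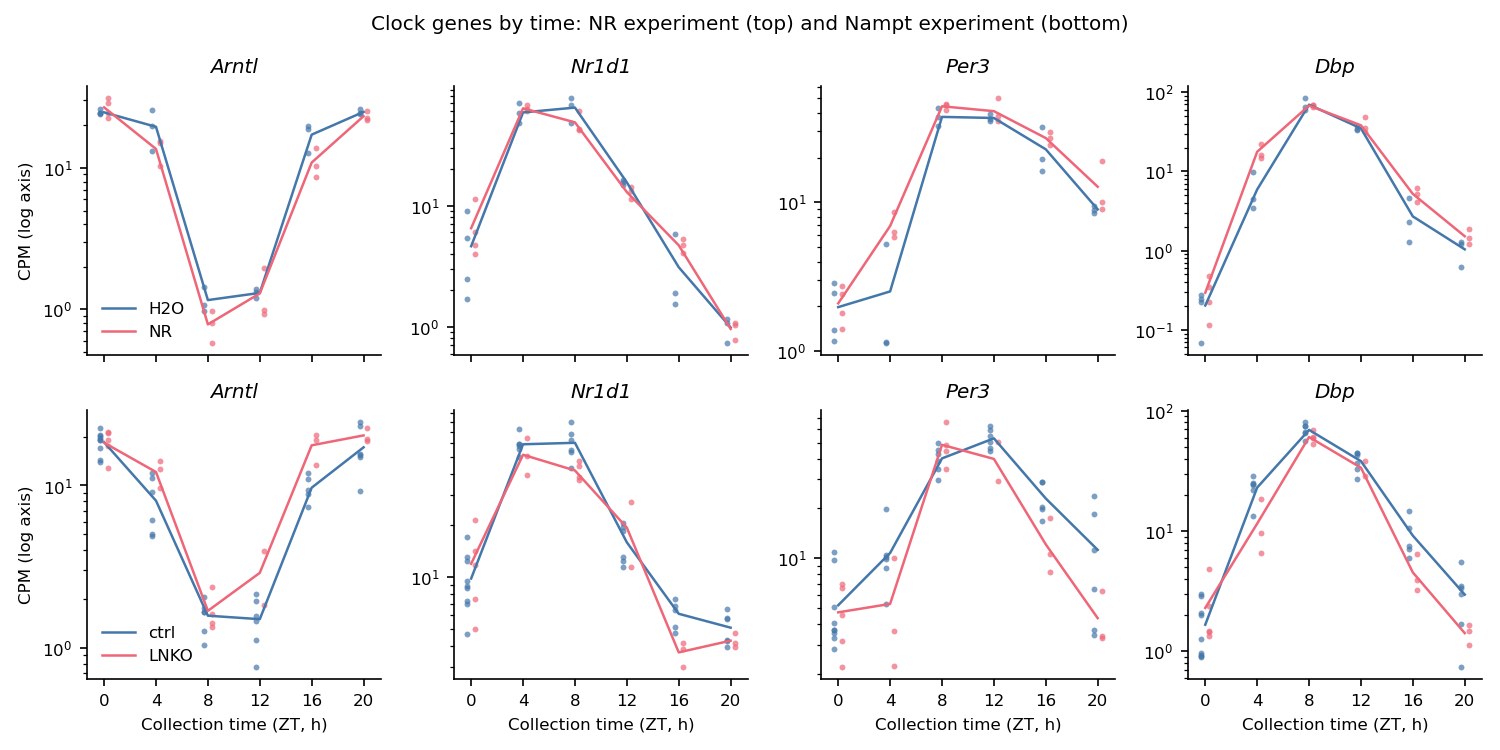
Counts per M counts (CPM, log axis) of Arntl, Nr1d1, Per3 and Dbp by zeitgeber time in hours, with H2O and NR libraries in the top panels and control and LNKO libraries in the bottom panels. Points are libraries and lines join the mean at each time, and Arntl peaked near ZT22 with both drinks and in the controls.

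The difference between NR and H2O depended on the time of day for 4 genes. Zcchc24, which encodes a zinc finger protein, was 1.99-fold lower with NR at ZT12 (log2 fold change -0.99, SE 0.11, adjusted p = 2.77e-06, n = 3 per drink), and its log2 fold changes at the other times lay between -0.09 and 0.16. Its interaction test gave an adjusted p of 0.000578. Hnrnpa3, an RNA-binding protein, and St5 had interaction adjusted p of 0.0408 each, with the values that passed at ZT0 and ZT4 (Hnrnpa3, log2 fold changes -0.29 and -0.46) and at ZT16 (St5, -0.91). Of 25 ER stress and 21 acute-phase genes, 14 in each group varied by time when adjusted over the list alone and 0 over all genes by edgeR. For these 15710 genes edgeR gave 1889 at an unadjusted p under 0.05, and DESeq2 called 221. Without the filter on low counts edgeR called 1517, and with the replicate block 8. Without the H2O library of ZT0 replicate 1 the count was 1, and without the NR library of ZT12 replicate 1 it was 21, and leaving out any of 25 single libraries moved it by over 1.5 times.

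Deletion of Nampt, the enzyme that makes NMN in NAD+ salvage, was tested in livers of fasted mice. Nampt itself (chromosome 12, 32820335 to 32853369, GRCm38) was 5.85-fold lower in LNKO (log2 fold change -2.55, SE 0.07, adjusted p = 5.90e-34). Its level was 88.3 ± 29.2 CPM in controls (SD, n = 38, 54.1 to 154) and 15.2 ± 4.53 CPM in LNKO (SD, n = 20, 9.17 to 24.3), so that no LNKO library overlapped a control. Markers of bile duct cells rose most: 8 of 9 were higher and none lower (8 adjusted over the list alone), with a median log2 fold change of 1.08. Epcam, a surface protein of biliary cells, was 2.62-fold higher (log2 fold change 1.39, SE 0.14, adjusted p = 1.33e-10), Cd24a 2.40-fold (adjusted p = 1.94e-10) and Spp1, which encodes osteopontin, 2.12-fold (adjusted p = 1.94e-10). Of 14 stellate cell and fibrosis genes 7 rose (7 adjusted over the list alone), including the proteoglycans Lum at 1.58-fold and Bgn at 1.27-fold and the receptor Pdgfrb at 1.43-fold (adjusted p = 7.89e-05, 3.61e-05 and 0.000513). Outside the lists, Dpt, a matrix protein, rose 2.65-fold, Bicc1, an RNA-binding protein, 2.13-fold and Gsn, the actin-severing gelsolin, 2.08-fold (adjusted p = 3.50e-14, 5.48e-10 and 2.92e-10). The medians of other cell types in the same libraries were -0.04 for 15 endothelial, -0.10 for 17 macrophage, -0.33 for 10 lymphocyte, -0.44 for 6 erythroid and 0.59 for 5 neutrophil and monocyte markers. The cholangiocyte list passed camera with a preset correlation (adjusted p = 2.61e-27) and was called with an estimated correlation as well (adjusted p = 8.58e-06 with an estimated correlation), unlike the stellate list (9.42e-06, and adjusted p = 0.27 with an estimated correlation).

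Genes of several hepatocyte functions were lower in LNKO livers. Of 27 genes of xenobiotic metabolism 5 fell (11 fell and 1 rose adjusted over the list alone), among them the cytochrome P450 genes Cyp2c29 at 1.44-fold lower (log2 fold change -0.53, SE 0.08, adjusted p = 6.97e-06) and Cyp1a2 at 1.29-fold lower (adjusted p = 0.0183). Of 17 bile acid genes 4 fell (5 adjusted over the list alone). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.77-fold lower (log2 fold change -0.82, SE 0.23, adjusted p = 0.0142), and Sult5a1, a sulfotransferase, and Socs2, an inhibitor of growth hormone signalling, were 1.76-fold and 1.72-fold lower (adjusted p = 0.000616 and 0.00942). Among 28 NAD+ genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone), and besides Nampt these included Nmnat3, the mitochondrial adenylyltransferase, at 1.24-fold lower (adjusted p = 0.0102). Of 24 heat shock genes 3 rose by either adjustment, Cryab 1.5-fold, Serpinh1, a collagen chaperone, 1.29-fold and Hspb1 1.47-fold (adjusted p = 1.71e-05, 0.00101 and 0.0149). In total 1491 of 15867 genes differed, 806 up and 685 down, and 133 rose and 10 fell by over 2-fold. The xenobiotic (camera adjusted p = 0.000129), heat shock (0.00247), bile acid (0.00379) and NAD+ metabolism lists (0.00379) lost their calls, with adjusted p = 0.377, 0.727, 0.27 and 0.106 with an estimated correlation. Without LNKO ZT12 replicate 2, Cyp7a1, Cyp1a2 and Hspb1 missed the threshold (adjusted p = 0.0664, 0.0852 and 0.24). With the Alb-Cre controls alone the count was 752, Nmnat3 had an adjusted p of 0.0819 and Cyp7a1 one of 0.117.

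Clock outputs shifted in level in LNKO. Arntl was 1.36-fold higher (log2 fold change 0.44, SE 0.11, adjusted p = 0.00402) and Per3 1.5-fold lower (log2 fold change -0.58, SE 0.17, adjusted p = 0.0214), the only members of 16 core clock genes to change by either adjustment. Of 18 clock output genes 7 fell and 2 rose (10 and 2 adjusted over the list alone), with Wee1, a cell cycle kinase, 1.45-fold lower (adjusted p = 0.00133) and Lpin1, a phosphatidate phosphatase, 1.60-fold higher (adjusted p = 0.0221). The list was called down (camera adjusted p = 0.0093, and adjusted p = 0.178 with an estimated correlation). Without LNKO ZT12 replicate 1, Arntl and Lpin1 missed the threshold (adjusted p = 0.118 and 0.239), as did Lpin1 and Per3 without LNKO ZT4 replicate 3 (0.062 and 0.0512) and Per3 without LNKO ZT12 replicate 2 (0.0706). All 16 core clock genes were rhythmic in both arms, with Per1 at an adjusted p of 0.0396 in LNKO and 0.0958 without LNKO ZT4 replicate 3. Arntl peaked at ZT21.9 ± 0.26 h in controls (SE, n = 38) and ZT21.2 ± 0.39 h in LNKO (SE, n = 20), and Nampt had a peak-to-trough ratio of 2.27 in controls and 1.81 in LNKO. In all 7207 genes were rhythmic in controls and 5646 in the fewer LNKO libraries. With 1 control genotype alone, 3777 (Alb-Cre; Nampt+/+, n = 18) and 3634 (Namptfx/fx, n = 20) were rhythmic in controls. The counts thus do not show which arm had more rhythmic genes. The test of the difference called 1 gene, Gm6135 (adjusted p = 0.0132, chosen after its values were seen), at a mean log2 CPM of -0.469. By the same test 1442 genes had an unadjusted p under 0.05, and DESeq2 called 42. The count was 22 without LNKO ZT12 replicate 1 and 0 without LNKO ZT4 replicate 1 or with the Alb-Cre controls alone. Leaving out any of 12 single libraries moved it by over 1.5 times.

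**Figure D2:**
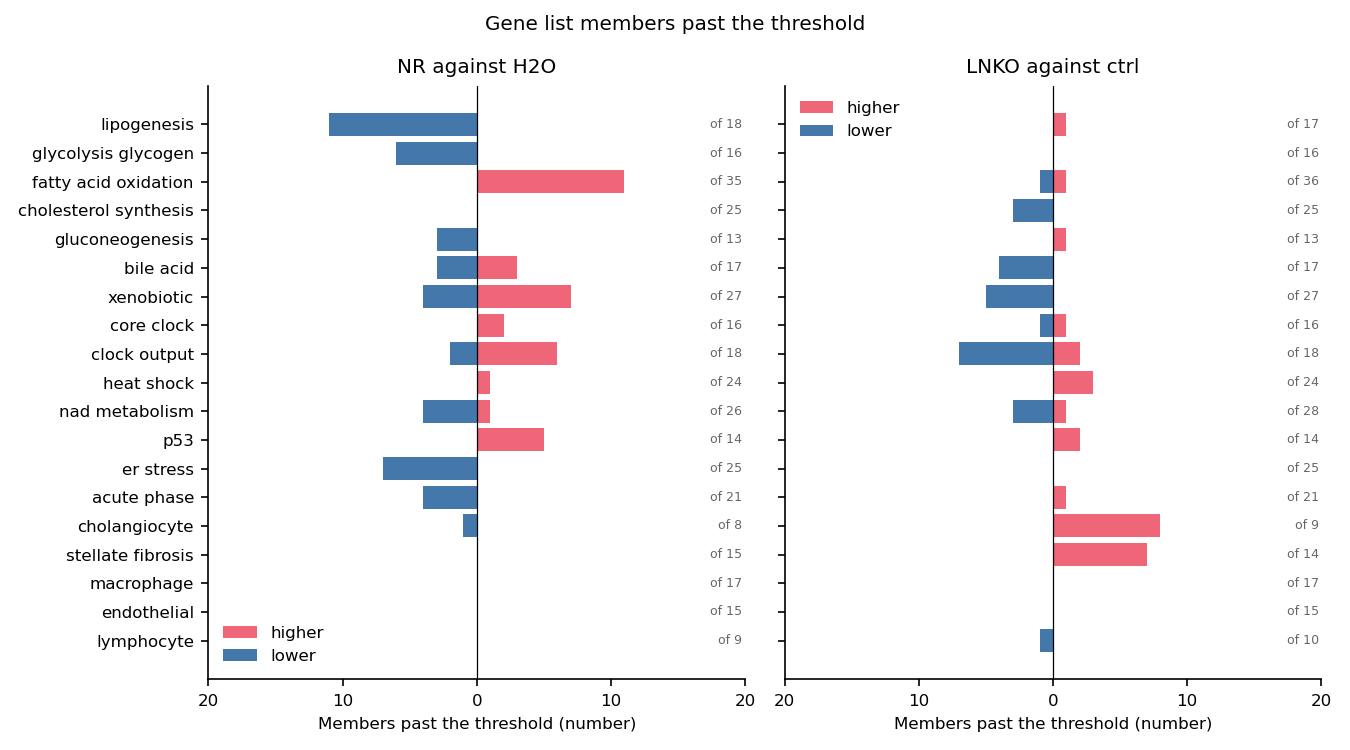
Number of members of 19 gene lists past the threshold, higher (right) or lower (left), for NR against H2O and for LNKO against controls, each as a mean over the 6 times. Bars start at 0, and 11 lipogenic genes were lower with NR while 8 of the bile duct markers were higher in LNKO.

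The effect of Nampt loss varied with time for 41 genes. Atp1b1, a subunit of the sodium pump, was 2.78-fold higher in LNKO at ZT16 (log2 fold change 1.47, SE 0.17, adjusted p = 2.12e-07, n = 3 LNKO and 5 control) and 1.52-fold higher at ZT20 (adjusted p = 0.0424), and the other times did not pass. Ciart, a repressor of the clock, was 5.47-fold lower at ZT4 (log2 fold change -2.45, SE 0.42, adjusted p = 0.000792). Pnpla2, the lipase that starts triglyceride breakdown, was higher at ZT16 and ZT20 (1.60-fold and 1.75-fold, adjusted p = 0.0225 and 0.00228), and the tight junction genes Cldn1 and Cldn3 were lower at ZT16 (1.89-fold and 1.75-fold, adjusted p = 0.00851 and 0.00396). Tdo2, which opens the path from tryptophan to NAD+, was 1.64-fold higher at ZT16 (adjusted p = 0.0154). Of 25 cholesterol synthesis genes 3 varied by time (20 adjusted over the list alone). By DESeq2 the count was 304, with 2136 genes at an unadjusted p under 0.05 by edgeR. It was 2 without LNKO ZT16 replicate 2, 453 without LNKO ZT12 replicate 1 and 3 with the Alb-Cre controls alone, and 18 single libraries moved it by over 1.5 times.

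The control arm pools mice with Cre and mice with the floxed allele, which were compared with each other. Nampt did not differ (log2 fold change 0.00, adjusted p = 1), and 34 of 15382 genes did, 16 higher and 18 lower in Alb-Cre; Nampt+/+ than in Namptfx/fx (n = 18 and 20). Of these, 20 lay within 25 Mb of Nampt on chromosome 12, where 147 genes were tested. They include Sntg2, a syntrophin, at a log2 fold change of -1.28 (SE 0.11, adjusted p = 2.07e-09), Acp1, a phosphatase, at 0.43 (SE 0.04, adjusted p = 2.07e-08) and Tmem18 at -0.55 (SE 0.07, adjusted p = 5.70e-06). On other chromosomes, Camk2b, a calcium-dependent kinase, was 1.34 higher on the log2 scale (SE 0.23, adjusted p = 0.00199) and Gstm6, a glutathione transferase, 0.41 higher (SE 0.08, adjusted p = 0.00488). Of the genes in this window, Nampt itself not taken out, 18 were called between LNKO and both controls pooled. Against the Alb-Cre controls 25 were called, and against the Namptfx/fx controls 5. With replicate number as a block the count of 34 became 1, since the numbers of the controls follow their genotype.

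**Figure D3:**
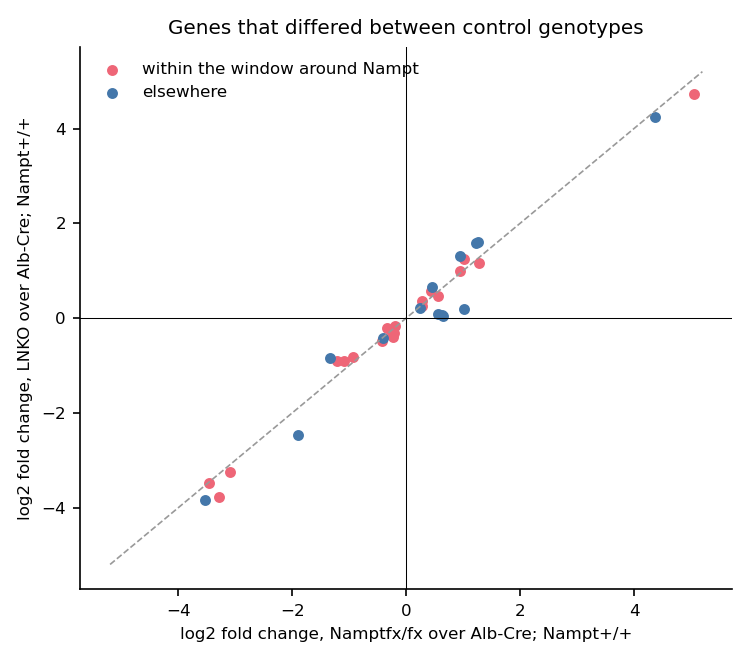
Genes that differed between the control genotypes, with the log2 fold change of Namptfx/fx over Alb-Cre; Nampt+/+ on the x axis and of LNKO over Alb-Cre; Nampt+/+ on the y axis. Each point is a gene, red within 25 Mb of Nampt and blue elsewhere, and the dashed line marks equal values, with 20 of the 34 genes near Nampt.

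The knockout of Bmal1, a transcription factor of the core clock, was compared with wild type in saline at ZT6 (n = 3 each). Counts at Arntl (chromosome 7, 113207465 to 113314126), the gene of Bmal1, were 5.38-fold higher in libraries labelled Bmal1 KO (log2 fold change 2.43, SE 0.30, adjusted p = 0.00118), at 9.07 to 10.7 CPM against 1.00 to 2.46 CPM. These counts merge all exons, so they do not show whether the deleted part is missing. Known Bmal1 targets were far lower: Nr1d1 by 43.1-fold (log2 fold change -5.43, SE 0.33, adjusted p = 1.66e-05), Dbp by 27.7-fold (adjusted p = 8.27e-05), Nr1d2 by 13.3-fold (adjusted p = 3.91e-07) and Per3 by 8.49-fold (adjusted p = 0.000294). Npas2, the paralog of Clock, was 188-fold higher (adjusted p = 5.54e-06) over 4 to 8 counts per wild-type library, and Cry1, a repressor, 6.30-fold (adjusted p = 2.22e-05). Of 16 core clock genes 6 rose and 6 fell (8 and 6 adjusted over the list alone), and the median of 0.44 and mean of -0.41 differ in sign, with a camera direction of down (adjusted p = 0.853). Of 18 clock output genes 4 rose and 6 fell (4 and 11 adjusted over the list alone), with Cdkn1a, a cell cycle inhibitor, 46.2-fold higher (adjusted p = 0.000154) and Gys2, the liver glycogen synthase, 2.66-fold lower (adjusted p = 0.00251).

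**Figure D4:**
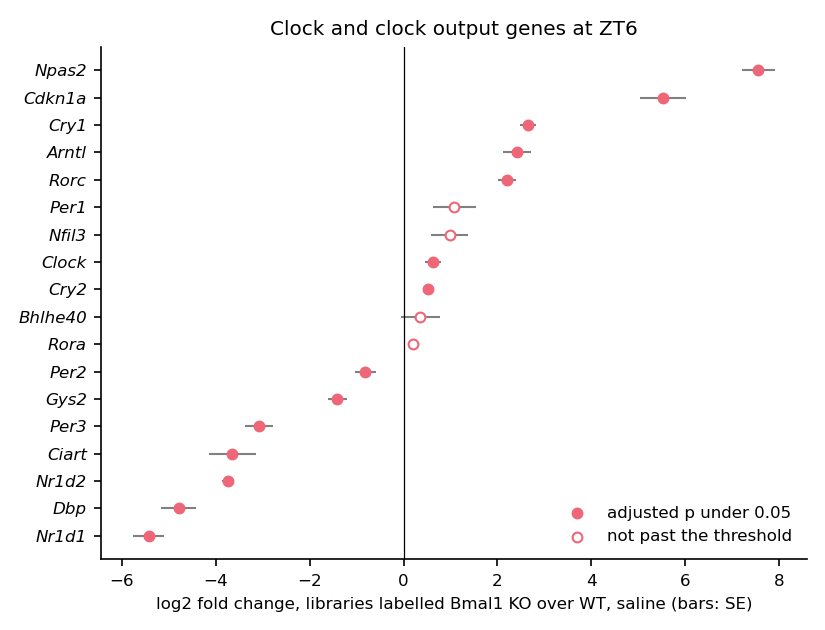
Log2 fold change (± SE) of clock and clock output genes in Bmal1 knockout over wild-type livers in saline at ZT6, n = 3 each. Core clock genes other than Bhlhe41 are shown, with the 3 clock output genes of smallest p in this comparison. Filled points have an adjusted p under 0.05, with Nr1d1 at -5.43 and Npas2 at 7.56.

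Metabolic and translation genes also differed in Bmal1 knockout livers. Of 25 cholesterol synthesis genes 17 rose and none fell (19 adjusted over the list alone, median 1.29), with Hmgcs1, which makes HMG-CoA, 5.46-fold higher (log2 fold change 2.45, SE 0.41, adjusted p = 0.00585), Lss 4.44-fold (adjusted p = 0.00298) and Mvk 3.06-fold (adjusted p = 0.00631). Of 79 ribosomal protein genes 58 rose and none fell (75 adjusted over the list alone, median 0.40). Of 35 fatty acid oxidation genes 5 fell and 1 rose (11 and 2 adjusted over the list alone), including Aldh3a2, a fatty aldehyde dehydrogenase, at 3.79-fold lower (adjusted p = 0.0003) and Fabp1, the liver fatty acid carrier, at 2.66-fold lower (adjusted p = 0.00157). Sult1e1, the estrogen sulfotransferase, Loxl4, a lysyl oxidase, and Ntrk2, a neurotrophin receptor, were 172-fold, 60.4-fold and 60.1-fold higher (adjusted p = 5.54e-06, 1.66e-05 and 0.000759). Hspb1 fell 9.28-fold (adjusted p = 4.98e-05), Nt5e, an enzyme that splits nucleoside monophosphates, rose 4.30-fold (adjusted p = 0.00742), and Nampt was 1.99-fold lower (adjusted p = 0.0277, and 0.0975 without WT saline replicate 1, with other single libraries also ending the call). In all 1908 genes differed, 1083 up and 825 down, and DESeq2 called 2602. The ribosomal protein (camera adjusted p = 2.37e-20), cholesterol synthesis (7.21e-13) and fatty acid oxidation (0.000483) calls gave adjusted p = 0.739, 0.739 and 0.744 with an estimated correlation. Leaving out 1 library gave 962, 768 and 1020 genes (WT saline replicates 1, 2 and 3) and 1103 and 935 (KO saline replicates 1 and 3).

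The same livers were used to ask what NMN did with and without Bmal1, over saline, in 2 NMN libraries per genotype. Arntl had a log2 fold change of 0.03 in wild type (SE 0.35) and 0.14 in the knockout (SE 0.30). In wild-type livers none of the 17338 genes passed, so the values below are of gene groups and of genes that did not pass. Of 28 interferon-response genes 0 fell over all genes and 12 adjusted over the list alone (median -0.46), with Zbp1 at -1.46 (SE 0.25, adjusted p = 0.198). The 79 ribosomal protein genes had a median of 0.23 and the 16 core clock genes one of 0.37 (0.23 without wild-type NMN replicate 1), with Cry2 at 0.68 (SE 0.09, adjusted p = 0.198). The 15 stellate cell and fibrosis genes had a median of 0.92 (0 rose over all genes, 6 adjusted over the list alone), and -0.08 without wild-type NMN replicate 2. The 6 erythroid markers had one of 0.98, and -0.22 without wild-type NMN replicate 1. In knockout livers the median of 25 cholesterol synthesis genes was -0.99 (0 fell over all genes, 19 adjusted over the list alone) and that of 17 macrophage markers -1.04 (0 and 16). The 21 acute-phase genes had a median of 0.87 (0 rose over all genes, 10 adjusted over the list alone), and 0.27 without knockout NMN replicate 1. That library stood apart, with 1936 CPM of Saa1, 267 CPM of Lcn2 and 90.4 CPM of Sirt1, the last against 10.3 to 16.9 CPM in the other 9 libraries. The interaction medians, knockout minus wild type, were -1.0 for cholesterol synthesis (-0.64 without wild-type NMN replicate 2), -1.05 for macrophage and 1.11 for acute-phase genes (0.62 without knockout NMN replicate 1). For stellate cell and fibrosis genes the interaction median was -1.28 (0 of 15 fell over all genes, 7 adjusted over the list alone), and -0.77 without wild-type NMN replicate 2. Their median in the knockout was -0.64, with -0.18 without knockout saline replicate 1 and -1.14 without knockout NMN replicate 1. The 10 lymphocyte markers had medians of -0.70 in the knockout and -0.85 for the interaction (0 fell by either adjustment). These medians were 0.02 and -0.08 without knockout NMN replicate 1, and -1.97 and -2.01 without knockout NMN replicate 2. edgeR called 0 genes in wild type, 0 in the knockout and 0 for the interaction, with 1501, 2095 and 2064 at an unadjusted p under 0.05. DESeq2 called 99, 285 and 61, and edgeR without the filter on low counts 586, 1073 and 1012. Without knockout NMN replicate 2 the knockout count was 236 and the interaction count 119, and without wild-type NMN replicate 1 the wild-type count was 1. The interferon and ribosomal lists (camera adjusted p = 7.44e-20 each), the core clock list (3.77e-05), the stellate list (4.30e-07) and the erythroid list (0.00934) in wild type gave adjusted p = 0.125, 0.677, 0.125, 0.677 and 0.864 with an estimated correlation. The cholesterol (2.77e-18), macrophage (2.49e-17) and acute-phase (7.22e-13) calls in the knockout gave adjusted p = 0.563 each with an estimated correlation, as did the lymphocyte call (0.0022), and the stellate call (0.000427) gave 0.628. The stellate and lymphocyte calls of the interaction (1.96e-09 and 0.0112) gave adjusted p = 0.571 and 0.773 with an estimated correlation.

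In the Sirt1 experiment, deletion of Sirt1, an NAD+-dependent deacetylase, was compared with fx/fx controls in saline. Sirt1 counts did not differ at the gene level (log2 fold change 0.09, SE 0.15, adjusted p = 1), at 15.4 ± 1.65 CPM in libraries labelled LSKO (SD, n = 3) and 14.5 ± 1.23 CPM in controls (SD, n = 4). Counts merged over exons do not show whether a part of the gene is missing. Acute-phase genes had a median of 0.57 in LSKO (0.25 without LSKO saline replicate 1) and lipogenic genes one of 0.49 (0.10 without LSKO saline replicate 2), and 5 erythroid markers, which point to blood in the sample, one of -1.05 (0 fell over all genes, 4 adjusted over the list alone). edgeR and DESeq2 each called 0 genes, with 441 at an unadjusted p under 0.05 by edgeR. The acute-phase, lipogenesis and erythroid lists were called by camera (adjusted p = 1.67e-13, 9.97e-07 and 1.69e-10), and gave adjusted p = 0.472, 0.565 and 0.154 with an estimated correlation.

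NMN was then compared with saline within each Sirt1 genotype. In fx/fx controls (n = 4 each) 5 genes rose and 1 fell. Nlrp12, a regulator of inflammation, was 3.78-fold higher (log2 fold change 1.92, SE 0.30, adjusted p = 0.0416), Cdip1, a p53-responsive gene, 1.95-fold (adjusted p = 0.0259), Cntrl, a centrosome protein, 1.69-fold and Cyp27a1, a sterol hydroxylase of bile acid synthesis, 1.45-fold (adjusted p = 0.0416 each). Eif4ebp3 (log2 fold change 2.82) and RP23-279O5.4 (-2.32), both at an adjusted p of 0.0258, were chosen after their values were seen. Of 21 acute-phase genes 0 rose over all genes and 19 adjusted over the list alone (median 0.97), with Serpina3n at 2.73 (SE 0.50, adjusted p = 0.0628), and 12 of 25 cholesterol synthesis genes fell adjusted over the list alone (0 over all genes, median -0.55). NMN replicate 2 of the controls stood apart, with 1371 CPM of Saa1 against 24.5 to 101 CPM in control saline libraries, 21.9 CPM of Arntl and 1.69 CPM of Dbp. In LSKO (3 saline, 4 NMN), lipogenic genes had a median of -0.69 (0 of 18 fell over all genes, 10 adjusted over the list alone), with Fasn, the fatty acid synthase, at -1.70 (SE 0.36, adjusted p = 0.311). In the same livers 9 bile duct markers had a median of -1.44 (0 fell over all genes, 5 adjusted over the list alone), against -0.71 in fx/fx (-0.37 without control saline replicate 3). The medians of 10 periportal, 5 erythroid and 8 female-biased genes in LSKO were 0.63, 0.77 and 1.12 (0 rose over all genes, 6, 4 and 3 adjusted over the list alone). The last was 0.49 without LSKO NMN replicate 3 and 2.91 without LSKO saline replicate 3. Nnmt, which methylates nicotinamide, was at 1.57 in LSKO (SE 0.31, adjusted p = 0.215). edgeR called 6 genes in fx/fx, 0 in LSKO and 0 for the interaction, with 1919, 1281 and 413 at an unadjusted p under 0.05 and 273, 34 and 1 by DESeq2. The count of 6 became 47 without control NMN replicate 1 and 0 without control NMN replicate 2 or 4 or control saline replicate 1 or 4, and 13 single libraries moved it by over 1.5 times. Without control NMN replicate 4 the LSKO and interaction counts were 1 each. The acute-phase and cholesterol calls in fx/fx (camera adjusted p = 1.78e-22 and 2.14e-13) gave adjusted p = 0.224 and 0.325 with an estimated correlation, the lipogenesis call in LSKO (1.58e-13) 0.142, and an interaction median of -0.64 for acute-phase genes (1.09e-11, and -0.28 without LSKO saline replicate 1) 0.402. The cholangiocyte, periportal, erythroid and female-biased calls in LSKO (1.03e-08, 4.57e-07, 0.000299 and 0.00153) gave adjusted p = 0.142, 0.156, 0.322 and 0.142 with an estimated correlation, and the cholangiocyte call in fx/fx (0.000906) 0.602.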

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

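The tests of clustering near Nampt, of a lower share of hepatocytes, of bile duct markers in each LNKO library and of pairs of NMN libraries were chosen only after the result was seen, as were the 4 sets of left-out libraries listed with the processing.

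Genes that differed between the control genotypes were clustered near Nampt: 20 of 34 lay within 25 Mb, against 147 of 15382 tested genes (Fisher exact p = 1.31e-32). The test takes genes as independent, which neighbours need not be, and some of the called gene models overlap. This p can therefore overstate the evidence. The 20 genes lay between positions 16988648 and 32979050, so that none was in the far part of the window beyond Nampt. LNKO livers carry both Cre and the floxed allele, so their position between Alb-Cre; Nampt+/+ (0) and Namptfx/fx (1) tells the sources apart. For the genes near Nampt the median position was 1.03 with a lower quartile of 0.883, which argues against Cre in hepatocytes as the source there and is consistent with strain variants carried along with the floxed allele, a hypothesis that shares its LNKO and control libraries with the pattern. For the 14 genes elsewhere the median was 0.988 with quartiles of 0.296 and 1.28, so that Cre and other differences between the lines cannot be told apart. LNKO calls near Nampt (18 with both controls, 25 with Alb-Cre alone, 5 with Namptfx/fx alone) may hold such variants. Nampt itself was not taken out of these counts. Over all genes, 1491 of 15867 (9.4%) were called with both controls, and whether the 18 exceed this share was not tested. A biological effect of Nampt loss on the called genes stays open.

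Markers of bile duct cells rose in LNKO (8 of 9, median 1.08). A lower share of hepatocytes would raise the markers of every other cell type alike. The highest median of the macrophage, endothelial and lymphocyte markers was -0.0379, which argues against it as the whole source. Other cell types were mixed, with medians of 0.59 for 5 neutrophil and monocyte markers (1 past the threshold) and 0.34 for 14 stellate cell and fibrosis genes. That of 6 erythroid markers was -0.44. A few libraries with more bile duct tissue are argued against by the level of the markers in each library, which in 20 of 20 LNKO libraries lay above the upper quartile of the controls (0.201 over the control mean of the same time; LNKO 0.223 to 1.59, highest control 0.368), and by 7 markers still past the threshold in the lowest of the fits with 1 LNKO library left out (without LNKO ZT16 replicate 2). The mixture of control genotypes is argued against by 7 past it in the lower of the fits against 1 genotype alone. A change in the bile duct compartment itself with loss of Nampt, which the design names, may explain the pattern but stays a hypothesis, as counts of bulk liver do not separate more cells from more RNA per cell.

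Few genes passed between NMN and saline in Sirt1 fx/fx livers (6). With the acute-phase deviation of each library from its group as a covariate, 97 genes passed, including all 6. In 50 random lists of the same size at most 68 passed. Members of a random list need not vary together as those of a response do. An acute-phase response in some libraries and other spread that many genes share thus cannot be told apart. With the first 2 components of the clock genes 113 passed, but 7 of 50 random lists gave as many (highest 152), so that different clock phase and general spread cannot be told apart. Without the 2 NMN libraries of another naming scheme (replicates 3 and 4) 0 genes passed, but this leaves 2 NMN libraries, and the other pairs left out gave 0, 0, 1, 41 and 189 (without replicates 1 and 2), so that a batch and the size of the arm cannot be told apart. A biological reason, such as a varied response to NMN or to injection, was not tested.

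Values below stood out and are given without explanation. In groups of 4 to 10 libraries, 3 of 50 tested sets held a library far from the others, where chance alone would mark about 1 in 20. The share of mitochondrial counts was 7.27% in ctrl ZT16 replicate 4 (nearest library 7.56%, n = 5), and the share of the 10 most abundant genes was 14.9% in ctrl ZT16 replicate 2 (nearest 15.8%, n = 5) and 18.1% in Sirt1 fx/fx NMN replicate 3 (nearest 16.5%, n = 4).

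Effects that differed between times, by interaction tests, were found for 4 genes with NR and 41 with LNKO, and 1 gene differed in rhythm between LNKO and controls. With NR, adjusted p were 0.000578 for Zcchc24 and 0.0408 for Hnrnpa3 and St5. Of 43 alternatives Hnrnpa3 missed the threshold in 21 and St5 in 19, and Zcchc24 in none. In LNKO, adjusted p were 0.000171 for Atp1b1, 0.00184 for Ciart, 0.0121 for Osbpl11, Pnpla2, Tmem87b and Cldn3, 0.0123 for Tdo2, 0.0135 for Npm3, 0.0148 for Prkd3 and 0.0163 for Cldn1. Of these 10 genes, Atp1b1 and Ciart passed under every alternative run, and the others missed the threshold without LNKO ZT16 replicate 2 and with the Alb-Cre controls alone.

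Libraries were also regrouped at random within each experiment to ask whether chance can be excluded. It can for NR against H2O (1791 genes, at most 19 in the other splits, 1 of 100 as large with the real one). The same holds for rhythm with H2O (5219, highest other 9) and NR (5569, highest other 8). LNKO against controls (1491, highest other 2, 1 of 50) and rhythm in controls (7207, highest other 408) and LNKO (5646, highest other 616) are alike. For NMN in Sirt1 fx/fx (6, highest other 1) only the real split was as large, 1 of 35. This is under a share of 0.05, but 35 splits can give no lower share, and many counts were tested alike. The control genotypes (34, 2 of 100 as large) were also under that share, although 1 other split called 75 genes. The splits alone thus do not exclude chance for either count. For effects that vary with time the splits cannot decide. They mix the arms at each time, which removes the mean difference between arms together with any dependence on time. This covers NR by time (4, highest other 5, 3 of 100), LNKO by time (41, highest other 16) and differential rhythm in LNKO (1, highest other 0, 1 of 50). The last count is 1 gene, Gm6135, at a mean log2 CPM of -0.469, and was 0 with the Alb-Cre controls alone. Of these counts, 4 rest on single libraries. With 1 library left out, NR by time gave 1 (H2O ZT0 replicate 1) to 21 (NR ZT12 replicate 1), LNKO by time 2 (LNKO ZT16 replicate 2) to 453 (LNKO ZT12 replicate 1), differential rhythm in LNKO 0 (LNKO ZT4 replicate 1) to 22 (LNKO ZT12 replicate 1) and NMN in Sirt1 fx/fx 0 (saline replicate 1 or 4 or NMN replicate 2 or 4) to 47 (NMN replicate 1), and 25, 18, 12 and 13 single libraries moved them by over 1.5 times. Where 0 genes passed, every split is as large by construction, so that the splits say nothing on chance: differential rhythm with NR (100 of 100; highest other 26), NMN in LSKO (35 of 35; 3), LSKO in saline (35 of 35; 0) and NMN by Sirt1 genotype (100 of 100; 11). For Bmal1 knockout against wild type (1908; highest other 3) the 10 splits are too few for a share under 0.05.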

How the results depend on the processing

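The fits without 2 ZT0 libraries, without the shallowest library, without ZT12 and without 2 Sirt1 fx/fx NMN libraries were chosen only after the data were seen. Of 573 alternative values of the counts, 455 stayed within 1.5 times, 57 were lower and 61 higher. Of 20142 values of named genes, 19457 kept their side of the threshold, 336 lost a call, 349 gained one and 0 reversed. With size factors in place of TMM no count moved by over 1.5 times. Where a value below differs, the cause was not tested, except that 1 genotype of controls holds fewer libraries, and the block takes up control genotype since the replicate numbers follow it. The shallowest library held 3.9 M counts, and leaving it out moved no count of the Nampt experiment by over 1.5 times.

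DESeq2 called 221 genes for NR by time, 29 for differential rhythm with NR, 304 for LNKO by time, 42 for differential rhythm in LNKO, 99 for NMN in wild type, 285 in Bmal1 knockout, 61 for their interaction, 273 for NMN in Sirt1 fx/fx, 34 in LSKO and 1 for their interaction. Without a filter the counts were 1517 for NR by time, 220 for LNKO by time, 8 for differential rhythm in LNKO, 193 for the control genotypes, 586 for NMN in wild type, 1073 in Bmal1 knockout, 1012 for the interaction, 2897 for Bmal1 knockout against wild type, 79 for NMN in Sirt1 fx/fx and 1 in LSKO. With the replicate block they were 8 for NR by time, 2 for differential rhythm in LNKO, 1 for the control genotypes, 1199 for Bmal1 knockout and 3 for NMN in Sirt1 fx/fx. With time as 6 levels, the test of differential rhythm is the same as the interaction with time. Its counts of 4 with NR and 41 in LNKO thus repeat the interaction counts and say nothing further on differential rhythm. Without the ZT0 libraries numbered apart NR by time gave 2. Against Alb-Cre controls alone, LNKO gave 752 genes, 3 by time, 3777 rhythmic in controls and 0 of differential rhythm. Against Namptfx/fx controls alone there were 86 by time, 3634 rhythmic in controls and 9 of differential rhythm. Without ZT12, differential rhythm in LNKO gave 77. In 1 fit of 25 libraries, NMN gave 1 gene in Bmal1 knockout and 42 in Sirt1 fx/fx. Without the 2 libraries of another naming scheme it gave 0 in Sirt1 fx/fx and 2 in LSKO. With an estimated correlation 1 list was called in LNKO and 0 in the other 10 contrasts.

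Leaving out in turn each library of a group of up to 5 (25 of 58 for LNKO and controls, all elsewhere) gave 1 (H2O ZT0 replicate 1) to 21 (NR ZT12 replicate 1) genes for NR by time, 2 (LNKO ZT16 replicate 2) to 453 (LNKO ZT12 replicate 1) for LNKO by time, 0 (LNKO ZT4 replicate 1) to 22 (LNKO ZT12 replicate 1) for differential rhythm in LNKO, 0 to 1 (NMN replicate 1) for NMN in wild type, 0 to 236 and 0 to 119 (knockout NMN replicate 2) for NMN in Bmal1 knockout and the interaction, 768 (WT saline replicate 2) to 2027 for Bmal1 knockout against wild type, 0 to 47 (control NMN replicate 1) for NMN in Sirt1 fx/fx, and 0 to 1 (control NMN replicate 4) in LSKO and for the interaction. Counts that stayed within 1.5 times ran from 1404 to 2096 for NR, 1110 to 1766 for LNKO, 26 to 39 for the control genotypes, 4623 to 5355 (H2O), 4987 to 5769 (NR), 6949 to 7326 (controls) and 4891 to 5741 (LNKO) for rhythm, and 0 to 0 for differential rhythm with NR and for LSKO in saline.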

Other observations

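The tests below were chosen before their results were seen, except for the examples of genes and the fits that leave libraries out.

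Over all 4 genotypes that received NMN, 444 of 17793 genes differed from saline in 1 fit of 25 libraries, 178 higher and 266 lower (3170 at an unadjusted p under 0.05). Lipid synthesis genes were lower: 5 of 18 lipogenic genes fell (12 adjusted over the list alone, median -0.58) and 5 of 25 cholesterol synthesis genes (20 adjusted over the list alone, median -0.45), with Gpam, the first enzyme of glycerolipid synthesis, at -0.81 (SE 0.11, adjusted p = 0.00089). Of 28 interferon-response genes 6 fell (13 adjusted over the list alone, median -0.42). Of 13 gluconeogenic genes 2 rose and of 12 glucocorticoid targets 2 rose (7 and 6 adjusted over the list alone). Relative to the mean of their experiment, glucocorticoid targets were at 1.22 (log2) in Bmal1 knockout NMN replicate 1 and -0.06 in replicate 2. In Sirt1 fx/fx NMN livers they were at 1.60 in replicate 2 and -0.17 to 0.45 in the others. With saline they were at -1.325 to -0.10 in Sirt1 fx/fx and -0.34 to 0.93 in Bmal1 knockout livers. LSKO livers were at -0.72 to 0.07 with saline and -0.14 to 0.93 with NMN. Wild-type livers were at -0.81 to -0.44 with saline, and at 0.14 and -0.64 with NMN. Got1, an aspartate aminotransferase, was at 1.05 (SE 0.15, adjusted p = 0.00146). Of 21 acute-phase genes 4 rose (9 adjusted over the list alone, median 0.51), and their median was 0.22 without Bmal1 knockout NMN replicate 1 and Sirt1 fx/fx NMN replicate 2, which stood apart. In wild type alone, with 2 NMN libraries, the acute-phase median was -0.35 (-0.65 without NMN replicate 1 and -0.14 without NMN replicate 2), and that of cholesterol synthesis genes was 0.13, with 0.47 without NMN replicate 1 and -0.30 without NMN replicate 2. The medians of markers of other cell types were -0.39 for 17 macrophage, -0.46 for 9 bile duct and 0.49 for 6 erythroid markers, of which few passed (0 called over all genes, and 0, 2 and 0 adjusted over the list alone). Gpam and Got1 were chosen after their values were seen.

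The hypothesis there was that NMN changes a set of genes shared by the 4 genotypes. The test was of the mean effect over the genotypes, which a strong change in 1 of them can pass. Of 100 splits within genotypes 1, the real one, gave as many as 444 genes, and the highest other gave 5. Chance can thus be excluded for the mean effect, but whether the genotypes share it was not tested. The count was 107 without Bmal1 knockout NMN replicate 1, 149 without wild-type NMN replicate 1, 262 without LSKO saline replicate 2, 277 and 279 without wild-type saline replicates 2 and 3, 278 without Bmal1 knockout saline replicate 1, and 116 without both libraries that stood apart, 103 of them shared with the 444. A response to NMN in several of the genotypes may explain the pattern, but acute-phase values differed between libraries of 1 group, and the number of genes rests on single libraries.

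A second hypothesis was that NR and the loss of Nampt move liver genes in opposite directions. The LNKO mice and their controls were fasted for 18 h, whereas the NR and H2O mice carry no label of fasting. Across 1774 genes called with NR, the Spearman correlation between the fold changes was -0.31, and -0.11 over all 15321 genes (genes are not independent replicates), but 6 of 100 splits of the NR libraries gave a value as low as the former (lowest -0.392), so that chance could not be excluded. Of 215 genes called in both comparisons (159 by chance), 184 moved in opposite directions, 132 of them higher with NR and lower in LNKO, and 31 in the same one. Examples chosen after their values were seen are Per3 (0.47 with NR, -0.58 in LNKO), Dbp (0.60 and -0.47), Lpin1 (-0.48 and 0.68) and Cidec (1.55 and 0.89).

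The last was that oral NR and injected NMN move genes in the same direction. The sets differ in more than route, as NR was drunk for 4 months by mice of 8 months, and NMN injected at 4 to 6 months. NR values are means over 6 times in wild type, and NMN values means over 4 genotypes at ZT6. The Spearman correlation was 0.142 over genes called with NR and -0.0143 over all 15687 genes, and for the former 21 of 100 splits gave as high a value (highest 0.259), so that these data do not show it.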
